A study of Mus musculus with 6 samples.

How the data were processed

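Liver RNA of male C57BL/6 mice was sequenced after 71 weeks on either normal chow or chow that contained polyethylene microplastic (PE-MP). Per the labels, there were 6 libraries, 3 for each chow, made from total RNA by poly(A) selection with a kit that keeps the strand. Groups and replicate numbers were taken from the labels, which name each library as a separate replicate. The labels do not say that each library came from a different animal, so p-values measure the spread between these libraries, which may be technical. They give no batch, cage, litter or dose of PE-MP.

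The deposited values are raw counts per gene, whole numbers that were not normalised, as the totals and the file headers show. Per the submitters' processing notes, bcl2fastq was used and the genome build was GRCm39. The version of bcl2fastq, the aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Each file held 56674 rows, and the table of the whole series had the same values as the per-library files on all 56674 rows, so it gave no separate result. A symbol stood on more than 1 row for 67 symbols, and those 939 rows were kept apart; 36 of them were tested. Reads shared between mitochondrial genes and their nuclear copies, or between close paralogs such as Cyp4a12a and Cyp4a12b, could be divided or counted more than once by the counting, and values of such genes are uncertain. The reference annotation in use, GENCODE M21, belongs to build GRCm38 and holds 89.5% of the row symbols. It was used for gene type, number of transcripts, transcript length and GC content, and no coordinates are given.

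Differences between chows were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions, TMM factors and the default expression filter, which left 18043 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fold change is the log2 ratio of PE-MP chow to normal chow, and its 95% confidence interval came from the coefficient, its F statistic and the total degrees of freedom. For 16 tested genes with no count in 1 chow group the coefficient has no finite value; these carry edgeR's prior-count estimate, no standard error and no interval, and their fold is given as a bound against a floor of 3 counts per library. Levels are CPM values, scaled by the TMM factors, computed here from the deposited counts. Shares of counts, the levels of genes on in some libraries and off in others, and those of fat cell mRNAs set beside the fall of list members are of total counts and not scaled by these factors. Library shares were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1.

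Before the data were examined, 46 gene lists of pathways, cell types and complexes and a panel of 22 genes were fixed from textbook knowledge, as were the tests and most of the alternatives. The 44 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside an estimated correlation and fry. Named genes followed a rule fixed at the same time. It took up to 10 genes per direction with the largest change among those past the threshold whose groups did not overlap, or the 5 with the smallest p where fewer than 5 passed. It also took every panel gene, in values or summarised, and the members with the smallest p of each list, up to 4 for a list called by camera and up to 2 for any other. Named outside this rule were Alb, Rn18s-rs5, mt-Nd4, Trip11, Cep350, Bcl9l, Adipoq, Fabp4 and Plin1. A few genes that the rule selects, 3 of them in the panel, are not reported here by name; the panel counts include them.

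The edgeR and camera steps were tested on simulated counts with the means, library sizes and dispersions of these libraries, in 10 simulations with 200 changed genes each and 17567 genes per fit on average. For PE-MP chow against normal chow, 0.768% of genes changed by 1.5-fold, 6.96% of those changed by 2-fold and 52.5% of those changed by 4-fold passed the threshold. Of all calls, 11.9% were false, above the 5% aimed at, and 95.6% of the 95% intervals held the true value. Lists of 25 genes raised by 1.5-fold were called in 100% of cases with the preset correlation and in 94% with an estimated one, and unchanged lists in 2% and 0%. The simulated genes varied independently of each other, so the last figures do not cover lists whose members vary together.

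The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, no expression filter, a stricter one (CPM of at least 1 in all libraries of a group), each library left out in turn, the replicate number as a block, an adjusted p of 0.1, and leaving out genes over 1% of a library. Alternatives chosen after seeing the data left out genes that were on and off within a chow group, left out mitochondrial, 18S and pseudogene rows, dropped the robust option, or took a trend on transcript length and GC content out of each library. Total counts ran from 68357478 to 112566641 per library, and floors of 3 counts cover counting error only. The 95% intervals of fold changes also cover the spread between libraries.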

Results

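Hepatic transcript levels were measured by RNA sequencing in male C57BL/6 mice kept for 71 weeks on normal chow or on chow containing PE-MP, with 3 libraries per chow. The question was whether long exposure to the plastic alters gene expression in the liver. Normal chow libraries 1, 2 and 3 held 75897165, 68357478 and 112566641 counts. PE-MP libraries 1, 2 and 3 held 88266936, 75176645 and 91898953. Total counts did not separate the chows (exact permutation p = 0.9, n = 3 per chow).

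The make-up of the libraries differed between chows before any scaling. The 13 mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and the ATP synthase, took 14.6% ± 0.446 (SD, n = 3) of the counts under normal chow and 8.91% ± 0.279 (SD, n = 3) under PE-MP chow. A list of RNAs retained in the nucleus took 0.0321% ± 0.0163 and 0.0694% ± 0.0136, and Alb, the main plasma protein made by hepatocytes, took 4.79% ± 0.610 and 5.97% ± 0.250 (SD, n = 3 per chow). Genes with at least 1 count numbered 23551 ± 406 under normal chow and 25412 ± 466 under PE-MP chow. Each of these 4 measures parted the chows completely, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. Shares are parts of a whole, so a lower mitochondrial share by itself raises all others in the same proportion. The share of Alb rose 1.24-fold, and how much of that rise comes from the lower mitochondrial share was not tested. The ribosomal RNA gene Rn18s-rs5 took 2.92%, 11.2% and 1.15% of the counts in normal chow libraries 1, 2 and 3, and 5.98%, 3.10% and 0.334% in the PE-MP libraries. Normal chow library 2, with 11.2%, also stood apart on the first principal component across genes (0.61, against -73.6 and -69.3 for the other normal chow libraries and 45.1 to 49.4 for the PE-MP libraries).

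**Figure D1:**
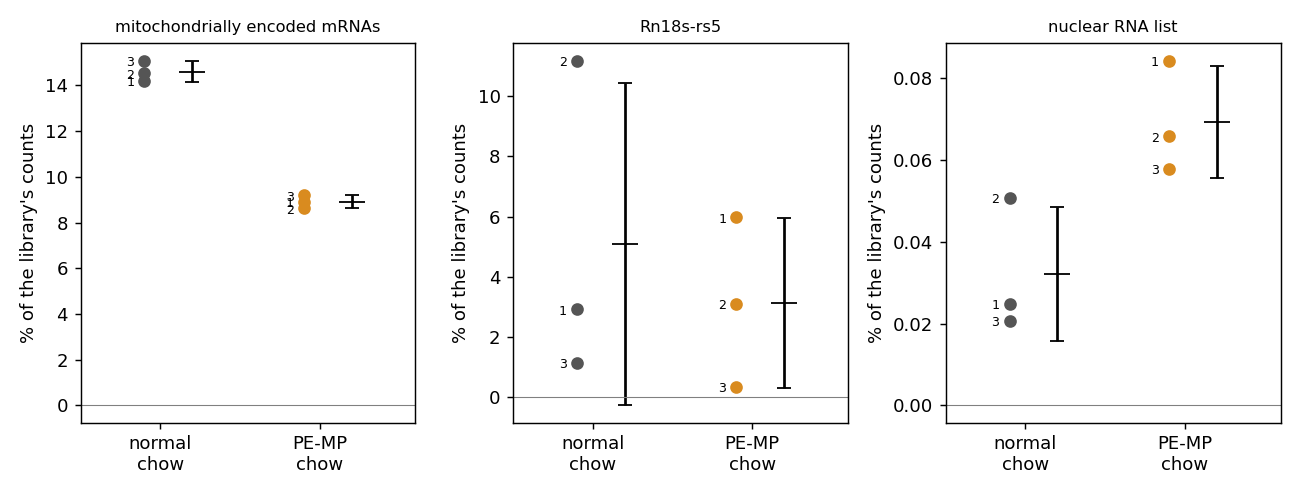
Share of each library's counts (percent, vertical axes) in the 13 mitochondrially encoded mRNAs, in Rn18s-rs5 and in the nuclear RNA list, for normal chow and PE-MP chow; points are libraries with their replicate numbers, and bars show the mean ± SD of 3, which for Rn18s-rs5 under normal chow reaches below 0. The mitochondrial mRNA share averages 14.6% under normal chow and 8.91% under PE-MP chow, and Rn18s-rs5 reaches 11.2% in normal chow library 2.

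At the level of single genes, Arhgap23 rose from 0.279 ± 0.0488 to 14.2 ± 3.05 CPM (SD, n = 3 per chow), a log2 fold change of 5.67 ± 0.27 (SE; edgeR adjusted p = 0.00313), and was higher in all 3 PE-MP libraries. With the replicate number as a block, a fit with fewer residual degrees of freedom, its log2 fold change was 5.65 and it did not pass (adjusted p = 0.160). It was the 1 gene of 18043 that passed the edgeR threshold upwards, and 0 genes passed downwards. The next genes by p, none of which passed, were Dennd5b (log2 fold change 5.81 ± 0.44), Gm28035 (2.71 ± 0.26), 1810019D21Rik (1.72 ± 0.17) and Lime1 (2.81 ± 0.28) in the upward direction, with edgeR adjusted p of 0.0531 for Dennd5b and 0.0599 for the others. In the downward direction they were Cyp4a12b, a male-biased fatty acid hydroxylase (log2 fold change -1.56 ± 0.14), Gm13341 (-1.12 ± 0.12), mt-Nd4l (-1.11 ± 0.12), Atp13a3 (-2.67 ± 0.29) and Gm28439 (-1.08 ± 0.12), each with an edgeR adjusted p of 0.0599. At an unadjusted p under 0.05 there were 3233 genes (17.9% of those tested, against 5% with no difference), 1642 higher and 1591 lower under PE-MP chow; without normal chow library 2 there were 5396, and without PE-MP library 2 there were 2150. The chows did not overlap for 4683 genes, 2558 higher and 2125 lower, or 26.0% of genes against 10% by chance.

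The count of single genes depended on the method and on 1 library. DESeq2 called 555 genes higher and 540 lower, and limma-voom called 7 and 12. Without normal chow library 2, edgeR called 452 genes higher and 623 lower. It called 2 higher and 1 lower without normal chow library 1 or PE-MP library 3, and 2 higher and 0 lower without PE-MP library 2. At an adjusted p of 0.1 on all libraries it called 24 and 29.

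The data also bound the size of change. For 8963 genes (49.7% of those tested) the whole 95% interval lay within 1 log2 unit of no change, and for 14597 (80.9%) it lay within 2 log2 units, a 4-fold change. In simulated counts with the spread of these libraries, 6.96% of genes changed by 2-fold and 52.5% of those changed by 4-fold passed the edgeR threshold.

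Among gene lists, 20 fell and 3 rose under PE-MP chow by camera with the preset correlation, of 44 tested. None of the 23 held with an estimated correlation, where the smallest adjusted p was 0.0620. That setting raised p even where the estimated correlation lay below the preset 0.01. For the aryl hydrocarbon receptor list (estimated correlation -0.026) the unadjusted camera p was 0.0289 with the preset and 0.0857 with the estimated correlation. The lost calls therefore cannot be put down to members varying together alone. By fry, which asks whether a list moves 1 way on balance, 1 list passed downwards, the mitochondrially encoded mRNAs.

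The mitochondrially encoded mRNAs fell together, with a median log2 fold change of -1.02 and all 13 members negative (camera adjusted p = 5.63e-26; adjusted p = 0.0620 with an estimated correlation). With adjustment over the list alone, 12 members were lower, and over all genes 0 were. The member mt-Nd4 was uneven within a chow, at 442, 308 and 29.6 CPM of total counts in PE-MP libraries 1, 2 and 3. It stood at 375, 989 and 539 in normal chow libraries 1, 2 and 3. The cytochrome oxidase subunit mt-Co1 went from 53020 ± 3575 to 23763 ± 595 CPM (log2 fold change -1.16 ± 0.13), mt-Co2 had a log2 fold change of -1.05 ± 0.12 and the ATP synthase subunit mt-Atp6 one of -1.02 ± 0.13. Nuclear genes of oxidative phosphorylation also fell, by less, with a median of -0.38 and all 38 members negative (camera adjusted p = 9.69e-11; adjusted p = 0.474 with an estimated correlation). When adjusted over the list alone, 11 of these were lower, against 0 over all genes, and examples are Cox6b1 (log2 fold change -0.79 ± 0.17), Uqcrq (-0.64 ± 0.14) and Ndufa5 (-0.61 ± 0.11). The cytosolic ribosomal proteins fell with a median of -0.20 in 46 members (camera adjusted p = 9.47e-06; adjusted p = 0.474 with an estimated correlation). In this list 0 were lower adjusted over the list alone or over all genes. With a trend on transcript length and GC content taken out, an alternative chosen after seeing the data, the ribosomal protein call ended (camera adjusted p = 0.694) and the median was 0.0046. The oxidative phosphorylation median moved to -0.20 with that trend taken out, and its call held (camera adjusted p = 6.72e-05). The nuclear RNA list rose with a median of 1.15 in 8 members (camera adjusted p = 0.00189; adjusted p = 0.474 with an estimated correlation), of which 0 were higher adjusted over the list alone or over all genes. Rian, at 0.220 ± 0.104 CPM (SD) under normal chow and 0.537 ± 0.249 under PE-MP chow, had a log2 fold change of 1.31 ± 0.51.

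Genes of fatty acid and triglyceride synthesis fell, with a median log2 fold change of -0.63 and 19 of 23 members negative (camera adjusted p = 5.75e-05; adjusted p = 0.474 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 higher, against 0 over all genes. The stearoyl-CoA desaturase Scd1 went from 5856 ± 2154 to 1577 ± 698 CPM (log2 fold change -1.89 ± 0.41), Scd2 had a log2 fold change of -1.41 ± 0.31 and the glycerol-phosphate acyltransferase Gpam one of -0.73 ± 0.15. Mlxipl, which codes for the carbohydrate-responsive activator ChREBP, went the other way (1.38 ± 0.18). Cholesterol synthesis fell with a median of -0.38 (camera adjusted p = 0.000853; adjusted p = 0.514 with an estimated correlation). Of its 25 members, 4 were lower adjusted over the list alone against 0 over all genes, including Hmgcs1 (log2 fold change -0.71 ± 0.15) and Nsdhl (-1.24 ± 0.27). Without normal chow library 3 this call was lost (camera adjusted p = 0.0567; median -0.12), and the median was -0.23 without normal chow library 1 and -0.62 without normal chow library 2. Lipid storage and uptake fell with a median of -0.25 (camera adjusted p = 0.00181; adjusted p = 0.474 with an estimated correlation). In that list, 0 of 19 members were lower adjusted over the list alone or over all genes. The monoglyceride lipase Mgll had a log2 fold change of -0.97 ± 0.23. The median of this list was -0.49 without normal chow library 2, -0.45 without PE-MP library 1 and -0.37 without PE-MP library 3. The lipoprotein list fell with a median of -0.15 (camera adjusted p = 0.0151; adjusted p = 0.505 with an estimated correlation), with Apoc4 (log2 fold change -0.79 ± 0.16) as the 1 member of 21 lower adjusted over the list alone, against 0 over all genes. The median was -0.0054 without normal chow library 1, where the call was lost, and -0.27 without normal chow library 2. The call was also lost without normal chow library 3 (median -0.18) and with the length and GC trend taken out (median -0.16; camera adjusted p = 0.218), where the median was no smaller.

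Targets of NRF2 and antioxidant enzymes fell, with a median log2 fold change of -0.49 and 28 of 31 members negative (camera adjusted p = 4.51e-12; adjusted p = 0.405 with an estimated correlation). With adjustment over the list alone, 9 were lower, against 0 over all genes. The glutathione transferases Gstm3 (log2 fold change -2.30 ± 0.29), Gsta1 (-1.81 ± 0.23) and Gstm1 (-1.22 ± 0.20) and the lipid peroxide reductase Gpx4 (-0.99 ± 0.19) had the smallest p. Targets of the xenobiotic receptors CAR and PXR fell with a median of -0.38 (camera adjusted p = 0.00106; adjusted p = 0.487 with an estimated correlation). Here 4 of 29 were lower adjusted over the list alone against 0 over all genes, with Cyp2b10 at a log2 fold change of -2.34 ± 0.51 and Cyp2c55 at -1.77 ± 0.31. This call was lost without normal chow library 3 (camera adjusted p = 0.0731; median -0.31). Male-biased liver genes fell with a median of -0.13 (camera adjusted p = 0.000948; adjusted p = 0.474 with an estimated correlation). In this list 3 of 38 were lower adjusted over the list alone and 0 over all genes: Cyp4a12b, Cyp4a12a (log2 fold change -1.51 ± 0.26) and Selenbp2 (-0.97 ± 0.13). Without normal chow library 2 that call was lost (camera adjusted p = 0.227; median 0.025), and without normal chow library 1 the median was -0.27. With the length and GC trend taken out the call held (camera adjusted p = 0.0296) but the median turned to 0.011. Pericentral hepatocyte genes fell with a median of -0.25 (camera adjusted p = 0.0168; adjusted p = 0.580 with an estimated correlation). Among them, 0 of 27 were lower adjusted over the list alone or over all genes, and the call was lost without normal chow library 3 (median -0.13) or PE-MP library 3 (median -0.19). Without normal chow library 2 the median was -0.43.

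Kupffer cell markers rose, with a median log2 fold change of 0.63 and 17 of 18 members positive (camera adjusted p = 5.75e-05; adjusted p = 0.474 with an estimated correlation). When adjusted over the list alone, 3 were higher, against 0 over all genes: Clec1b (log2 fold change 1.01 ± 0.18), Vsig4 (0.75 ± 0.20) and the lysosomal glycoprotein Cd68 (0.65 ± 0.15). Liver endothelial cell markers rose with a median of 0.36 and 23 of 24 members positive (camera adjusted p = 0.00189; adjusted p = 0.474 with an estimated correlation). In that list, 0 were higher adjusted over the list alone or over all genes. The scavenger receptor Stab1 had a log2 fold change of 0.83 ± 0.19, and the list median was 0.21 without PE-MP library 2. B and plasma cell markers fell with a median of -0.76 (camera adjusted p = 0.000359; adjusted p = 0.487 with an estimated correlation). Here 6 of 22 were lower adjusted over the list alone against 0 over all genes, such as Jchain, the joining chain of secreted antibodies (log2 fold change -3.38 ± 0.82), Mzb1 (-2.66 ± 0.66) and Cd79a (-1.37 ± 0.31). T and NK cell markers fell with a median of -0.62 (camera adjusted p = 0.00214; adjusted p = 0.514 with an estimated correlation) and genes of MHC class II antigen presentation with one of -0.34 (camera adjusted p = 0.00522; adjusted p = 0.505 with an estimated correlation). Adjusted over the list alone, 0 of 24 and 2 of 10 were lower, against 0 over all genes. All 3 of these lymphoid and antigen presentation calls were lost without normal chow library 2 (camera adjusted p = 0.128, 0.0619 and 0.118), with medians of -0.28 for B and plasma cells, -0.58 for T and NK cells and -0.25 for MHC class II. The MHC class II call was also lost with the length and GC trend taken out (camera adjusted p = 0.0533; median -0.24). The B and plasma cell median was -0.47 with the replicate block and -1.39 with the stricter filter, and the T and NK cell median -0.98 without PE-MP library 1. Stellate cell and fibroblast markers fell with a median of -0.34 (camera adjusted p = 0.00106; adjusted p = 0.514 with an estimated correlation) and extracellular matrix genes with one of -0.31 (camera adjusted p = 0.00181; adjusted p = 0.514 with an estimated correlation). For these, 0 of 24 and 0 of 38 were lower adjusted over the list alone or over all genes. Both were lost without PE-MP library 2 (camera adjusted p = 0.0775 and 0.0731; medians -0.19 and -0.12), and the stellate cell median was -0.54 without PE-MP library 3. Adipocyte genes fell with a median of -0.41 (camera adjusted p = 0.000359; adjusted p = 0.474 with an estimated correlation), also with Retn at its bound; the median was -0.20 without PE-MP library 1 and -0.63 without PE-MP library 3. Retn, which codes for resistin, at 0.262 ± 0.0814 CPM under normal chow and 0 counts under PE-MP chow, was at least 8.16-fold lower against a floor of 3 counts per library, and was the 1 member of 10 lower adjusted over the list alone, against 0 over all genes. The next members by p were Cfd, which codes for the complement protease adipsin (log2 fold change -2.99 ± 0.87), and the genes of the lipid droplet proteins Cidec (-1.89 ± 0.60) and Cidea (-2.59 ± 0.99), which fatty hepatocytes also express.

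Cell cycle genes fell, with a median log2 fold change of -0.68 and 30 of 36 members negative (camera adjusted p = 6.75e-08; adjusted p = 0.405 with an estimated correlation). With adjustment over the list alone, 2 were lower, against 0 over all genes: Cdc20, an activator of the anaphase-promoting complex (0.922 ± 0.130 against 0.179 ± 0.0465 CPM), and the spindle protein Tpx2 (log2 fold change -1.48 ± 0.32). With the stricter filter the median was -0.23 and the call held (camera adjusted p = 0.0305). Interferon-stimulated genes fell with a median of -0.35 (camera adjusted p = 0.000437; adjusted p = 0.474 with an estimated correlation). In this list 12 of 40 were lower and 2 higher adjusted over the list alone, against 0 over all genes. Ifi27 (log2 fold change -1.13 ± 0.15) and Bst2 (-0.97 ± 0.16) were on the lower side, and the chemokine Cxcl11 (1.06 ± 0.18) on the higher side. The interferon median was -0.20 without PE-MP library 2 and -0.53 without PE-MP library 3. The acute phase list fell with a median of -0.16 (camera adjusted p = 0.0151; adjusted p = 0.588 with an estimated correlation). Of its members, 0 of 28 were lower adjusted over the list alone or over all genes. Hamp, which codes for the iron hormone hepcidin, had a log2 fold change of -1.03 ± 0.23. That call was lost without normal chow library 1 or 3 (medians -0.14 and -0.12), without PE-MP library 3 (median -0.14) and with the length and GC trend taken out (camera adjusted p = 0.105; median -0.075). Without normal chow library 2 the median was -0.32.

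The other 21 lists did not pass. Neutrophil markers had a median log2 fold change of 0.85 in 8 members (camera adjusted p = 0.0607), with S100a9 at 1.53 ± 0.27 and 2 members higher adjusted over the list alone against 0 over all genes. The level of S100a9 was low, at 0.349 ± 0.0426 CPM (SD) under normal chow and 1.01 ± 0.175 under PE-MP chow. Inflammatory cytokines, chemokines and NF-kB targets had a median of 0.54 in 19 members (camera adjusted p = 0.0651). Hepatocyte identity genes had a median of 0.00 in 26 members (camera adjusted p = 0.690). Of these, 2 were higher adjusted over the list alone against 0 over all genes, among them Foxa1 (log2 fold change 3.28 ± 0.60). Foxa1 stood at 0.546 ± 0.298 CPM (SD) under normal chow and 5.36 ± 2.68 under PE-MP chow. Genes of fatty acid oxidation and PPAR alpha targets had a median of -0.05 in 31 members (camera adjusted p = 0.241).

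**Figure D2:**
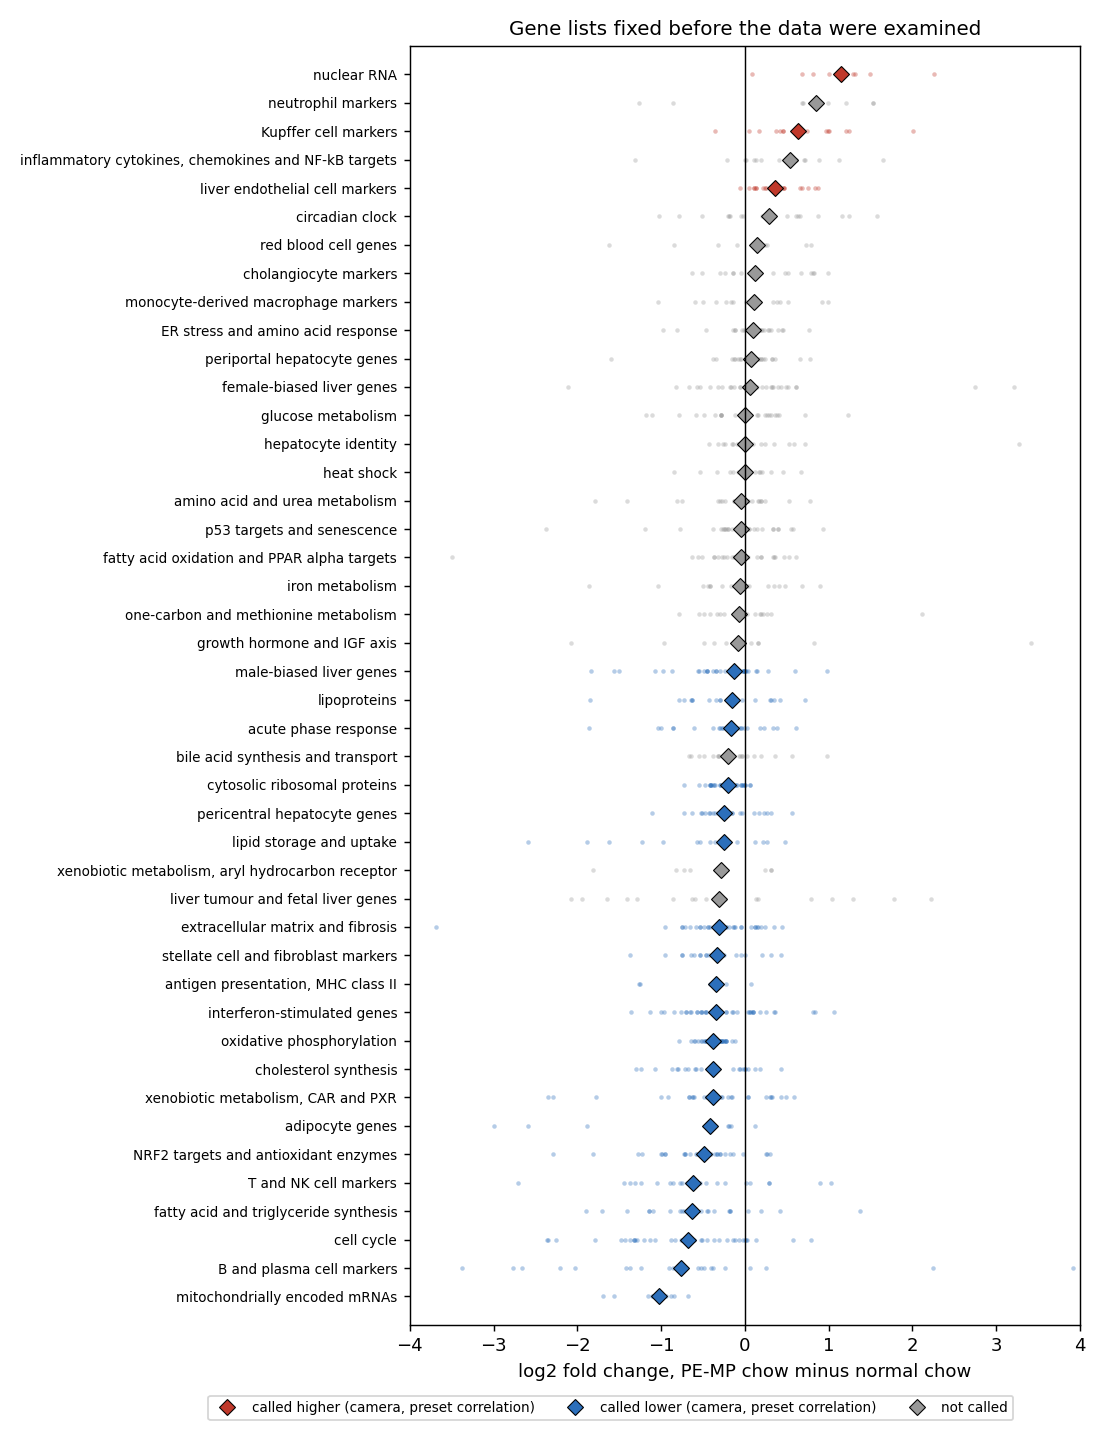
Log2 fold change of PE-MP chow over normal chow (horizontal axis) for the 44 tested gene lists; small points are member genes within 4 log2 units and diamonds are list medians, red where camera with the preset correlation called the list higher, blue where lower and grey where it made no call. Medians run from -1.02 for the mitochondrially encoded mRNAs to 1.15 for the nuclear RNA list, and none of the coloured lists held with an estimated correlation.

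Of the panel of 22 metabolic, xenobiotic and inflammatory genes, 0 passed the threshold over all genes with edgeR, and 2 passed adjusted over the list alone, Scd1 and Cyp2b10, both on the lower side. At an unadjusted p under 0.05 there were 5 panel genes on the lower side, including Fasn (log2 fold change -0.89 ± 0.31) and Cyp3a11 (-0.45 ± 0.16), and 1 on the higher side. The interval lay within 1 log2 unit for 8 panel genes, such as the fatty acid oxidation enzyme Cpt1a (-0.21 to 0.59) and the serum amyloid gene Saa1 (-0.84 to 0.25), and excluded a 4-fold change for 17. Acaca, at 4.25 ± 7.12 CPM under normal chow, varied too much between libraries for its change to be measured (95% interval -5.19 to 2.91).

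**Figure D3:**
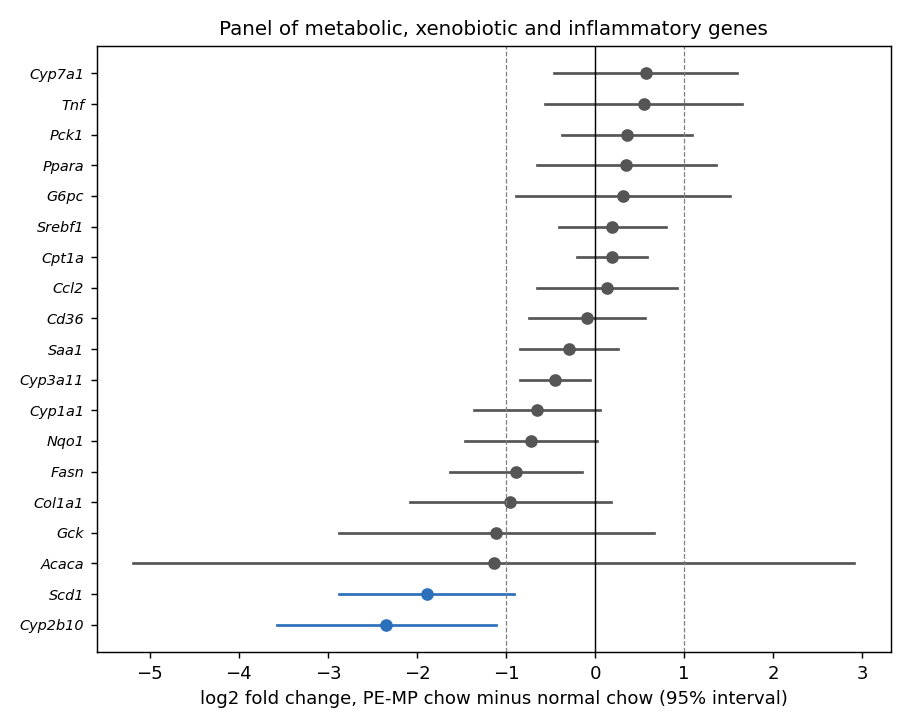
Log2 fold change of PE-MP chow over normal chow with its 95% interval (horizontal axis) for 19 of the 22 panel genes, from 3 libraries per chow; blue marks the genes that passed adjusted over the list alone, and dashed lines mark 1 log2 unit. Scd1 (-1.89) and Cyp2b10 (-2.34) are the 2 blue genes, and 14 of the intervals shown exclude a 4-fold change.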

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

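The alternatives without genes on and off within a chow group, without mitochondrial, 18S and pseudogene rows, without the robust option, with the length and GC trend taken out, and the block with an estimated correlation were chosen after the results were seen. The count of genes with a 95% interval within 1 log2 unit stayed within 1.5 times of 8963 in every alternative run, from 7662 to 9625. The count of called genes did not hold, from 1 higher and 0 lower: it was 2 and 1 with RLE factors, 555 and 540 with DESeq2, 7 and 12 with limma-voom, 11 and 28 with sample quality weights, 15 and 8 without a filter, 11 and 11 with the stricter filter, 24 and 29 at an adjusted p of 0.1, 2 and 1 without on and off genes, 2 higher without the robust option and 2 higher with the trend taken out. Leaving out 1 library gave 1 to 452 genes higher and 0 to 623 lower; both high values came without normal chow library 2. DESeq2 and that fit shared 494 genes, and all 19 limma-voom calls were DESeq2 calls. The cause was not tested. Correlations of deviations across genes were 0.00, 0.04 and 0.14 between same-numbered libraries. Between different numbers they ran from -0.15 to 0.12, so pairing by number was neither shown nor excluded. With the number as a replicate block 0 genes were called higher and 0 lower, and 3 lists higher and 21 lower.

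Of the list calls, 3 higher and 20 lower, 0 and 0 held with an estimated correlation. The same was true with the block or with the trend taken out, each with an estimated correlation. With the block, a fit with fewer residual degrees of freedom, the mitochondrial mRNAs had a camera adjusted p of 1.10e-22 with the preset correlation. It was 0.594 with the block and an estimated correlation, so the 0 calls of that setting say little about the lists. Fry gave 0 and 1. Leaving out 1 library gave 3 to 4 lists higher and 15 to 20 lower. With the trend taken out, 5 were higher and 18 lower. The ribosomal protein, MHC class II, acute phase and lipoprotein calls were lost there, with medians of 0.0046, -0.24, -0.075 and -0.16 (from -0.20, -0.34, -0.16 and -0.15), and neutrophil, inflammatory, bile acid and aryl hydrocarbon receptor lists passed.

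Signs reversed for some results that had not passed, and for the ribosomal protein genes Rplp1 (0.079) and Rps15 (0.0055) with the trend taken out. The log2 fold change of Acaca was 1.25 with limma-voom, 0.84 with quality weights and 2.14 with the replicate block. Without 1 library, the ranges were -1.73 to 3.76 for Acaca, -0.20 to 0.30 for Ccl2, -0.31 to 0.11 for Cd36, -0.29 to 0.55 for G6pc and -0.039 to 0.47 for Srebf1. The direction of the list test turned for heat shock (median -0.0028 with fry, 0.019 with the stricter filter), for cholangiocyte markers (-0.22 with the stricter filter) and for monocyte-derived macrophages (0.11 without mitochondrial rows). Without 1 library it turned for lists whose medians ranged from -0.17 to -0.0016 (amino acid metabolism), -0.0026 to 0.16 (ER stress), -0.094 to 0.40 (female-biased genes), -0.075 to 0.12 (heat shock), -0.082 to 0.026 (hepatocyte identity), -0.031 to 0.19 (monocyte-derived macrophages), -0.16 to 0.043 (one-carbon metabolism), -0.0055 to 0.20 (periportal genes) and -0.061 to 0.30 (red blood cell genes).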

Other observations

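Tests chosen only after the result was seen were those of nuclear RNA dilution, TMM scaling and batch for the mitochondrial mRNAs, of the hepatocyte share and fat tissue for the synthesis and NRF2 lists, and the count of genes on and off within a chow group. Genes outside the report's groups also differed between chows without passing the threshold. The glucokinase regulator Gckr had a log2 fold change of 1.24 ± 0.24, the transferrin receptor Tfrc one of 0.90 ± 0.21, and the leukaemia inhibitory factor receptor Lifr one of -0.97 ± 0.21 (edgeR adjusted p = 0.128, 0.139 and 0.135); each was the same way in all 3 libraries of a chow and passed adjusted over the list alone.

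Fold changes followed transcript length. Over 13470 nuclear protein-coding genes, Spearman's rho across genes was 0.313 with transcript length and -0.187 with GC content, where genes are not independent replicates; the median log2 fold change was -0.18 over the 3370 genes with the shortest transcripts and 0.17 over the 3368 with the longest.

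The mitochondrially encoded mRNAs were lower under PE-MP chow. Against the length and GC trend, they kept a median residual of -1.06 ± 0.06 (SE over 13 mRNAs). In these libraries that trend was thus not the whole source. The errors in this paragraph treat member genes as independent and leave out the spread between libraries. Dilution by nuclear RNA would lower cytosolic mRNAs alike. By contrast, the mitochondrial median lay 0.87 log2 units below that of the ribosomal protein and hepatocyte identity lists (difference -0.87 ± 0.06, SE over members). TMM scaling as the whole source is excluded by the unscaled shares (log2 ratio -0.71). The TMM factors averaged 0.901 under normal chow and 1.11 under PE-MP chow, which added to the fall in the scaled values (median -1.02). The labels give a batch, date, lane or run for 0 libraries, so a library or dissection batch that follows the chow cannot be told apart from the chow. An effect of PE-MP chow itself stays open and untested.

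Some genes were on in some libraries and off in others. A gene counts as on or off here when libraries differ by at least 10-fold with at least 10 CPM of total counts in the higher ones; 167 genes did so within a chow group, which chow cannot have set, and examples chosen after their values were seen are Cep350, at 0.266 CPM in PE-MP library 2 against at least 13.4 in the other libraries, and Bcl9l, at 0.059 in normal chow library 2 against at least 13.5. Chow parted 3 such genes, Arhgap23, Dennd5b and Trip11, against at most 1 in the other 9 splits, so chow may set the state of those 3, while the kind of switching seen within chow groups remains another possible explanation for them. Cell types of uneven abundance stay open. Of the 167 genes, 2.40% (exact 95% interval 0.656 to 6.02) belonged to cell type lists, but only 68 of the 7783 genes with at least 10 CPM in a library (0.874%) did, so the share was bound to be low and excludes nothing. Read assignment among transcript models stays open too: the rate of such genes was 1.07 times as high with 5 or more annotated transcripts as with 1 or 2 (95% interval 0.665 to 1.72).

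The fatty acid synthesis and NRF2 target lists were lower under PE-MP chow. In these libraries the length and GC trend was not the whole source, with a median residual of -0.51 ± 0.09. Nor was a lower share of hepatocytes, with a difference of -0.53 ± 0.09 from the hepatocyte identity list. The errors in this paragraph are SE over member genes, which treat members as independent and leave out the spread between libraries. No single library set the change, since the median stayed at or below -0.49 whichever was left out. The lipid droplet genes Cidea and Cidec of the adipocyte list had lower means under PE-MP chow as well, and like Fasn they were lowest among the normal chow libraries in library 2 (Cidea 84.4, 13.5 and 67.8 CPM; Fasn 100, 41.9 and 70.3). Fat tissue in the liver pieces stays open. The fat cell mRNAs Adipoq, Fabp4, Plin1, Cfd and Retn together reached 16.0 CPM of total counts in normal chow library 3, not below the median fall of the lists' members (11.5 ± 4.63). They also disagreed. Cfd, at 11.2 of the 16.0 CPM, averaged 7.17 CPM under normal chow and 1.12 under PE-MP chow, and Retn 0.236 and 0. Fabp4 averaged 3.92 and 4.27 CPM. Adipoq had 0, 0 and 2 counts in normal chow libraries 1, 2 and 3, and Plin1 had 0 in each. In PE-MP libraries 1, 2 and 3 Adipoq had 10, 0 and 5 counts and Plin1 7, 0 and 5. Adipoq and Plin1 thus were not higher under normal chow, where the lists were higher, while Cfd and Retn were. A batch that follows the chow and an effect of the chow both stay open too.

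The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. At the adjusted threshold, 3 of the 10 splits, the real one and 2 others, gave 1 gene each and the rest gave 0. At an unadjusted p under 0.05 the real split gave 3233 genes and the highest other 1160. For lists called by camera with the preset correlation, 1 of the 10 splits, the real one, gave 23, and the highest other split gave 21. Every other split mixed the chows unevenly, so it still carried part of any difference between chows. With normal chow library 1 and PE-MP libraries 2 and 3 on 1 side, the camera p of the mitochondrial mRNAs was 1.22e-07.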
